A study of Gallus gallus with 15 samples.

How the data were processed

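RNA was measured in the germinal disc region, which includes the small patch of cytoplasm on the yolk that holds the oocyte's chromosomes. Pieces of this region carry granulosa cells as well, and their share in each pool was not measured. The discs came from the largest preovulatory (F1) follicle of White Leghorn laying hens. Hens received corticosterone, testosterone or the peanut oil vehicle. Each of the 3 groups had 5 libraries, 15 in all, and each library was made from RNA pooled over several hens. The series design and the source names give 8 discs per pool, whereas the extraction protocol gives 9, so the number is uncertain. The replicates are described as biological replicates. The p-values below measure the spread between pools, and the spread between single hens was not measured.

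The authors deposited 1 table of raw read counts per gene, with 24881 Ensembl chicken gene identifiers and 15 columns. All columns matched a sample by their label, and 0 rows named no gene. TopHat2 2.0.14 and HTSeq 0.6.1p1 are named in the submitters' processing notes, without their settings. The kit was a strand-specific Illumina TruSeq kit, per the labels' protocols. The genome build, the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical paralogs may therefore be assigned differently from their origin, and this was not examined.

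The deposited table does not pair its identifiers with gene names. The reference table of chicken genes used here (assembly bGalGal1.mat.broiler.GRCg7b) matched 0 of the 24881 identifiers. Before the data were examined, 27 gene lists had been fixed, covering chromosome segregation, hormone responses, stress and cell type markers, together with a rule that named genes by symbol. Neither could be applied, so no list was tested and no gene is named by symbol. In their place, the identifier with the smallest p in each direction was taken for each comparison, which gave 6 identifiers. The 2 of smallest p in each direction among these are printed. This rule was chosen after the data were examined.

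Total counts per library ran from 24550108 to 33795073 in 14 libraries and were 12913729 in testosterone replicate 5. A gene entered the test if it passed edgeR's filterByExpr by group, which kept 14260 genes holding 99.95% of the counts. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood fit with 1 mean per group over all 15 libraries. The residual degrees of freedom were 12. The 3 pairwise contrasts and an F test of any difference among the 3 groups were tested, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are given as CPM, that is counts divided by the TMM-scaled library total and brought to a common total. Standard errors and 95% intervals of log2 fold changes were derived from the quasi-likelihood F statistic and apply to each gene alone. For genes with few reads they can be narrower than edgeR's own p allows. Principal components were computed from log2 CPM of the tested genes with a prior count of 2.

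The test was checked on simulated counts drawn with the means, depths and dispersions of these libraries. In each of 5 draws per comparison, 200 genes with a mean count of at least 50 were changed in 1 group. Genes were drawn independently of each other. The share called depends on how many genes change, so it may not carry over to data with fewer changes. Whether 2 libraries could be 1 library deposited more than once was checked by a chi-square test of their counts over genes with a summed count of at least 20. Its value per degree of freedom lay between 5.54 and 48.8 over the 105 pairs, where sampling noise alone gives about 1, so all libraries were kept as separate replicates.

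Single values per library were compared by exact two-sided permutation tests over the 252 assignments of 10 libraries, whose smallest possible p is 0.00794. These were 18 tests, adjusted together. A gene was counted as far above the median library where its CPM, plus 0.5, was at least 4 times the median over the libraries, plus 0.5.

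The alternatives were RLE, upper-quartile and no scaling, no low-count filter and a stricter one (at least 1 CPM in 5 libraries and a mean count of 20), a fit without robust estimation, a fit of only the groups compared, the replicate number as a block, 1 surrogate variable (sva 3.50.0), limma 3.58.1 voom with sample weights, DESeq2 1.42.0, a threshold of 0.1, and leaving out each library in turn. All of these were fixed before the data were examined. Fits without corticosterone replicates 1 and 2, and without these and testosterone replicate 2, were chosen after seeing the data.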

Results

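The germinal disc region of the F1 follicle was profiled by RNA sequencing in hens given corticosterone (1.5 mg), the main glucocorticoid of birds, testosterone (1.5 mg), the principal androgen, or oil alone (0.5 ml). The injection was given 5 h before the predicted ovulation and tissue was taken about 1.5 h later, 3.5 h before ovulation. The stated question was whether either hormone altered genes that govern how chromosomes segregate. The deposited counts carry identifiers without gene names, so that question was addressed over all measured genes and not for segregation genes as a group.

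Total counts were 25480330, 33795073, 29079294, 24769610 and 25109230 in control replicates 1 to 5. They were 31401787, 24550108, 28899137, 33464398 and 25497496 in corticosterone replicates 1 to 5, and 28916043, 26647984, 25979882, 30390157 and 12913729 in testosterone replicates 1 to 5. Testosterone replicate 5 thus had the lowest depth. Of 24881 genes, 21002 had a count in at least 1 library. A mean of 18003.8 ± 154 genes (SD, n = 5) was detected in controls, 18087 ± 197 after corticosterone and 17802.6 ± 447 after testosterone. Counts were spread over many genes, and the most abundant gene took a mean of 2.15% of them. The biological coefficient of variation among pools was 9.32% in controls, 12.3% after corticosterone and 9.37% after testosterone.

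Scores on the first 2 principal components overlapped between the treatments (exact permutation p of 0.167 or more for each pair of groups and component). The first component held 21.3% of the variance. Corticosterone replicates 1 and 2 scored 26.6 and 34.5 on it and testosterone replicate 2 scored 8.75, whereas the other 12 libraries lay between -15.7 and 0.92. In corticosterone replicates 1 and 2, 27 and 24 genes lay at least 4-fold above the median library, and 19 genes were in both lists. Testosterone replicate 2 had 11 such genes, control replicate 1 had 2 and the remaining libraries had 0. The 27 genes raised in corticosterone replicate 1 summed to 630 CPM there, 523 CPM in corticosterone replicate 2 and 314 CPM in testosterone replicate 2. In the other 12 libraries they summed to between 58.4 and 95.2 CPM. The lowest edgeR adjusted p among them was 0.474 for corticosterone against control.

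**Figure D1:**
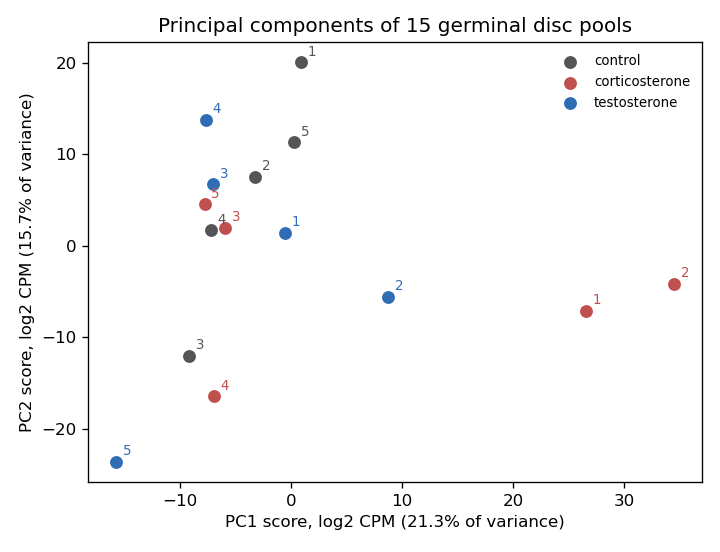
Scores of the 15 pools on the first (x axis, 21.3% of the variance) and second (y axis, 15.7%) principal component of log2 CPM, coloured by treatment and numbered by replicate. Corticosterone replicates 1 and 2 lie apart at 26.6 and 34.5 on the first component.

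**Figure D2:**
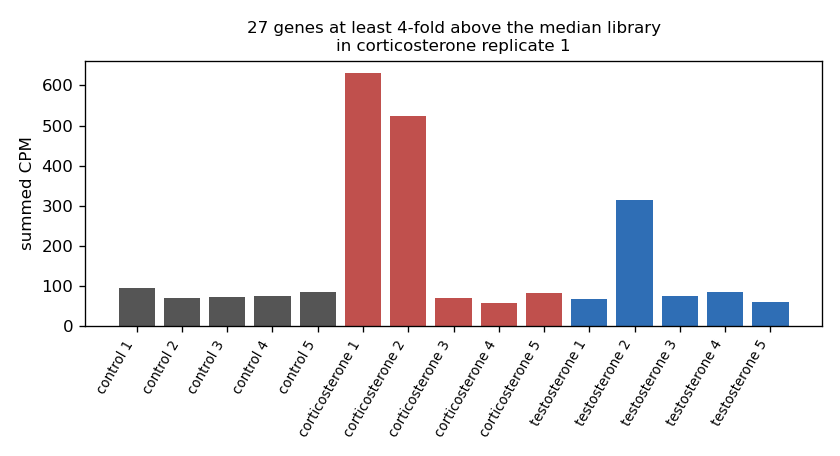
Summed level (y axis, CPM) of the 27 genes at least 4-fold above the median library in corticosterone replicate 1, as 1 bar per library, coloured by treatment. The sum was 630, 523 and 314 CPM in corticosterone replicates 1 and 2 and testosterone replicate 2 and at most 95.2 CPM elsewhere.

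Corticosterone against control asked whether the glucocorticoid altered germinal disc transcripts. With edgeR, 0 of 14260 genes passed the threshold, with a smallest adjusted p of 0.447. With limma voom 0 passed, and DESeq2, whose own filtering left an adjusted p for 2454 genes, called 13, all lower after corticosterone. At an unadjusted p under 0.05 there were 1346 genes, 533 higher and 813 lower, where a uniform distribution of p would give 713. ENSGALG00000009480 had the smallest p, at 28.1 ± 1.49 CPM after corticosterone and 36.6 ± 2.72 CPM in controls (SD, n = 5), a log2 fold change of -0.38 ± 0.070 (SE, edgeR adjusted p = 0.447). Its level was below the lowest control in all 5 corticosterone libraries, the highest of which was 30.4 CPM against 33.0 CPM for the lowest control. DESeq2 gave this gene an unadjusted p of 5.1e-07 but no adjusted p, so it could not be among the 13 calls. Genes whose 5 corticosterone and 5 control values did not overlap numbered 178, 83 higher and 95 lower, where chance gives 113.

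Among the 2171 genes over 100 CPM, 59 were higher and 276 lower after corticosterone at an unadjusted p under 0.05. The split was 63 higher and 260 lower with RLE and 92 higher and 246 lower with upper-quartile scaling. Only with libraries scaled by total count alone did it turn, to 244 higher and 138 lower. Among the 1634 genes under 1 CPM, 82 were higher and 34 lower, and 102 and 25 with total-count scaling. Over all genes the split was 1351 higher and 399 lower with total-count scaling, against 533 and 813 with TMM, and it was 802 and 800 without a low-count filter. The share of lower genes was 57.3% with RLE and 52.0% with upper-quartile scaling. The difference between genes over 100 CPM and genes of 1 to 10 CPM, taken within each library, averaged -0.03 ± 0.070 log2 units after corticosterone and 0.01 ± 0.039 in controls (SD, n = 5, exact permutation p = 0.286, adjusted p = 0.637). The 95% interval of the fold change lay within 1.5-fold for 11720 genes (82.2%) and within 2-fold for 13733 genes (96.3%), and wholly beyond 1.5-fold for 7 genes. In simulated data of this comparison with 200 changed genes of sufficient count, 81.6% of genes changed 1.5-fold and 96.4% of genes changed 2-fold were called. For genes changed by 0.32 log2 units the share was 50.4%, and a mean of 8 unchanged genes per draw was called as well. These shares hold for 200 genes changed at once and may be lower with fewer changed genes. Genes under 1 CPM were measured with less precision, and the interval lay within 1.5-fold for 12.5% of them. The count of 1346 fell to 825 without control replicate 1 and to 872 without corticosterone replicate 2, and was 2042 without corticosterone replicate 5.

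Testosterone against control asked the same of the androgen. No gene passed the threshold with edgeR (0 of 14260 genes, smallest adjusted p 0.750), limma voom (0) or DESeq2 (0). At an unadjusted p under 0.05, edgeR gave 485 genes, 265 higher and 220 lower, which was below the 713 of a uniform distribution, whereas limma voom gave 1024. ENSGALG00000026005 had the smallest p, at 3.16 ± 0.313 CPM after testosterone and 1.86 ± 0.366 CPM in controls (SD, n = 5), a log2 fold change of 0.76 ± 0.144 (SE, edgeR adjusted p = 0.750). All 5 testosterone values, from 2.80 CPM upwards, lay above the highest control of 2.40 CPM, and the corticosterone libraries averaged 1.96 ± 0.255 CPM. For this gene the adjusted p was 0.068 with DESeq2 and 0.393 with limma voom, and it passed the threshold in 0 of 28 alternative fits. Genes whose values did not overlap numbered 91, 52 higher and 39 lower, where chance gives 113.

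Genes over 100 CPM included 38 higher and 14 lower after testosterone at an unadjusted p under 0.05, and 25 and 16 with total-count scaling, and genes under 1 CPM included 28 higher and 40 lower. The interval of the fold change lay within 1.5-fold for 11880 genes (83.3%) and within 2-fold for 13730 genes (96.3%), and wholly beyond 1.5-fold for 0 genes. In simulated data of this comparison, 37.6% of genes changed by 0.32 log2 units, 84.8% of those changed 1.5-fold and 98.8% of those changed 2-fold were called. Without testosterone replicate 5, the library of lowest depth, the share of lower genes moved from 45.4% to 51.2%.

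**Figure D3:**
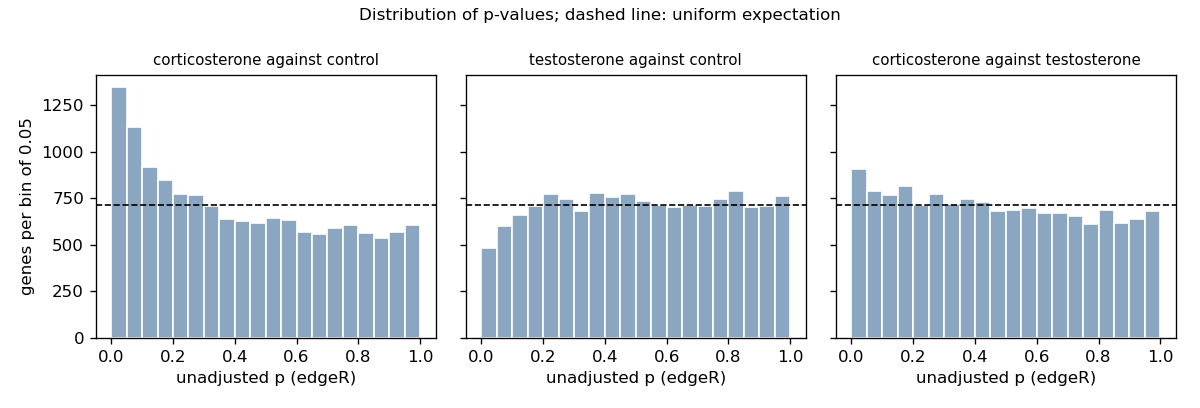
Number of genes (y axis) per bin of 0.05 of the unadjusted edgeR p (x axis) in each comparison, with the dashed line at the 713 genes of a uniform distribution. The first bin held 1346 genes for corticosterone against control, 485 for testosterone against control and 909 for corticosterone against testosterone.

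Corticosterone against testosterone compared the hormones directly. With edgeR, 0 of 14260 genes passed the threshold (smallest adjusted p 0.105), with 909 genes at an unadjusted p under 0.05, 294 higher and 615 lower after corticosterone. DESeq2 called 56 of the 9309 genes it gave an adjusted p, 2 higher and 54 lower, and limma voom called 2. ENSGALG00000043047 had the smallest p, at 30.5 ± 4.87 CPM after corticosterone and 45.7 ± 4.33 CPM after testosterone (SD, n = 5), with controls between them at 38.0 ± 2.93 CPM. Its log2 fold change was -0.58 ± 0.094 (SE, edgeR adjusted p = 0.105), and the highest corticosterone value of 37.8 CPM lay below the lowest testosterone value of 39.8 CPM. It passed the threshold in 7 of 28 alternative fits, with adjusted p between 3.65e-05 and 0.729 over all of them. ENSGALG00000009006, a gene of low abundance, was at 0.623 ± 0.102 CPM after corticosterone and 0.297 ± 0.063 CPM after testosterone (SD, n = 5), a log2 fold change of 1.08 ± 0.217 (SE, edgeR adjusted p = 0.158). Controls were at 0.457 ± 0.050 CPM.

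Genes over 100 CPM made up 12 of the higher and 193 of the lower genes in this comparison, and 74 and 117 with total-count scaling. Over all genes total-count scaling gave 770 higher and 357 lower, and upper-quartile scaling gave 397 higher and 492 lower. Values did not overlap for 169 genes, 44 higher and 125 lower, where chance gives 113. The interval of the fold change lay within 1.5-fold for 11676 genes (81.9%) and within 2-fold for 13688 genes (96.0%). In simulated data of this comparison, 82.0% of genes changed 1.5-fold were called. Calls appeared when 1 library was left out: 2 genes without control replicate 1, 5 without control replicate 4, 2 without corticosterone replicate 5 and 1 without testosterone replicate 2. Controls do not enter the means compared here, so leaving 1 out can act only through the shared spread, the scaling and the filter. The 909 genes became 1376 without corticosterone replicate 5 and 570 without corticosterone replicates 1 and 2.

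**Figure D4:**
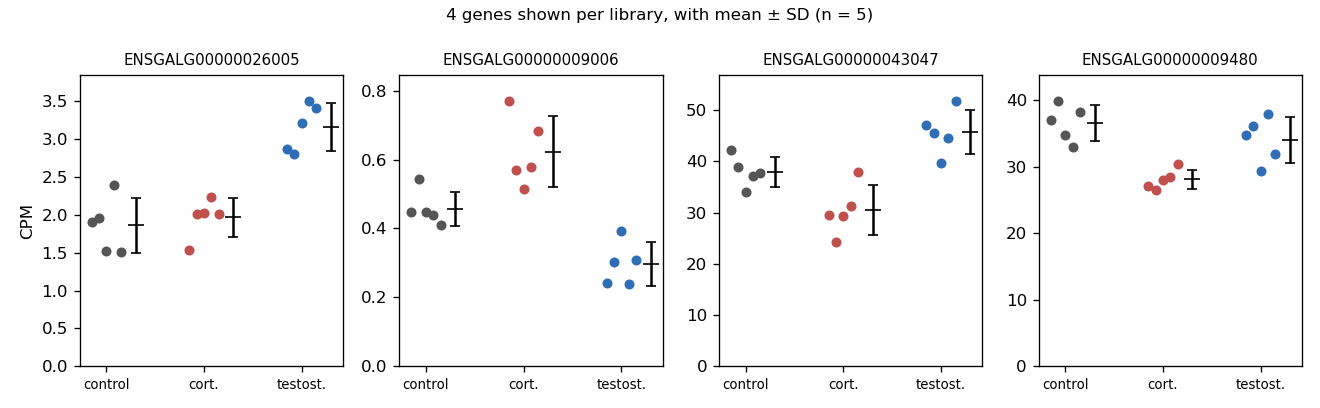
Level (y axis, CPM) of 4 genes in each library (points) by treatment (x axis), with the mean and SD of 5 libraries as a bar beside them. ENSGALG00000043047 lay between 24.3 and 37.8 CPM after corticosterone and between 39.8 and 51.7 CPM after testosterone.

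Tested together, the 3 groups gave 0 of 14260 genes past the threshold with edgeR (smallest adjusted p 0.307) and 939 at an unadjusted p under 0.05. Without corticosterone replicate 5, 1 gene passed and 1419 genes had an unadjusted p under 0.05. Genes read in all libraries of 1 group and in no library of another numbered 1 to 3 for each ordered pair of groups, with mean counts of at most 2.8.

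The log2 fold changes of the 2 hormones against the shared controls correlated across genes with Pearson's r of 0.550 and Spearman's rho of 0.452. Genes are not independent replicates. Counts were also simulated with no effect for all libraries, the shared controls included. They gave a mean r of 0.498 (range 0.474 to 0.518) and a mean rho of 0.458. The covariance was 0.0184 against a simulated 0.0137. The simulation drew genes independently and carried no structure among libraries beyond depth, so an excess over it does not show a hormone effect. With the controls divided so that each hormone had its own, the mean r over 20 divisions was 0.150 (range 0.046 to 0.249) and the mean rho was 0.058 (range -0.184 to 0.196). With the controls shared, r was 0.304 without testosterone replicate 2, against 0.550 with it.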

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

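The tests of genes far above the median library were chosen after the result was seen. Among 51 groups of 5 values tested for a value far from the others, 5 were found. Chance gives about 2.55 where values vary freely, which does not cover the 2 counts of genes whose other 4 libraries were all at 0, and the other 3 are linked measures of 1 library.

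Testosterone replicate 5 stood apart in depth, with 12913729 counts (12.9 M) against 25979882 in the next lowest testosterone library. It also had the fewest genes detected, 17032 against 17855 in the next. Its most abundant gene took 2.51% of its counts, against 2.16% in the next highest testosterone library. Control replicate 1 had 2 genes at least 4-fold above the median library, where the other controls had 0.

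Testosterone replicate 2 had 11 genes at least 4-fold above the median library, where the other testosterone libraries had 0. Together with 27 and 24 genes in corticosterone replicates 1 and 2 these formed one pattern, with 10 genes in all 3 lists. Counting noise is argued against by the 19 genes shared by corticosterone replicates 1 and 2, where independent lists would share 0.045. A corticosterone response common to all its pools is argued against by the other corticosterone libraries. There the highest median log2 excess of the 27 genes over controls was 0.0667, against 2.61 in replicate 1. These libraries already had 0 genes at least 4-fold above the median library, so a low excess was likely beforehand. A response that varied between corticosterone pools cannot be judged this way and stays open. Whether material of one kind was carried by some pools stays open, since the log2 excess over the control mean in corticosterone replicate 2 and testosterone replicate 2 correlated across the 27 genes with r of 0.681 (mean 0.625 with separate controls, range 0.487 to 0.764), while pairs among the 7 hormone libraries that do not stand apart reached 0.693 (mean 0.412) from the same controls.

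The counts of genes at an unadjusted p under 0.05 were set against other divisions of the same libraries, and each number of splits below includes the real one. For corticosterone against control, 13 of 100 splits gave at least the 1346 genes of the real one, and the highest other gave 2764. For testosterone against control 46 of 100 did, with 485 genes in the real split and 1989 in the highest other. For corticosterone against testosterone 31 of 100 did, with 909 and 2346 genes, and for any difference among the 3 groups 25 of 100 did, with 939 and 2518. The 56 genes called by DESeq2 for corticosterone against testosterone were reached in 5 of 30 splits, the real one included, the highest other giving 395. Chance could not be excluded for any of these counts. Past the edgeR adjusted threshold, where the real grouping gave 0 genes, some other splits did give genes. These were 5 splits for corticosterone against control (at most 84 genes), 1 for testosterone against control and 2 for corticosterone against testosterone (at most 1 gene each). The highest split gave 4.10 times the real count for testosterone against control. It gave 2.05 times for corticosterone against control and 2.58 times for corticosterone against testosterone. Each is the largest of many splits, and the real testosterone count was low, so the ratio alone does not show a structure of the samples. The 5 libraries highest on the second principal component all lay on one side of the highest testosterone split, against 4 of 5 in the highest split of either other pairwise comparison. A split picked for its count tends to follow a component of the same data, so this names no cause.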

How the results depend on the processing

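Only the fits leaving out several libraries together were chosen after the result was seen. The count of 0 genes held in 28 of 29 alternatives for corticosterone against control, 29 of 29 for testosterone against control, 21 of 29 for corticosterone against testosterone and 24 of 26 for any difference. DESeq2 gave 13 and 56 genes for corticosterone against control and against testosterone. All 13 and all 56 had an edgeR p under 0.05, and their edgeR adjusted p ran from 0.447 to 0.453 and from 0.105 to 0.387. For corticosterone against testosterone, limma voom gave 2 genes and no low-count filter gave 1. Leaving out 1 library gave 0 to 5 genes for corticosterone against testosterone (2 without control replicate 1, 5 without control replicate 4, 2 without corticosterone replicate 5, 1 without testosterone replicate 2), 0 to 1 for any difference (1 without corticosterone replicate 5) and 0 for the other comparisons. The cause was not tested, though a left-out control could act on corticosterone against testosterone only through the shared spread, the scaling and the filter. Leaving out corticosterone replicates 1 and 2 together, or these and testosterone replicate 2, gave 0 genes throughout.

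With the replicate number as a block, 4 genes passed for corticosterone against testosterone, 1 for any difference and 0 for the other comparisons. The labels do not say whether equal numbers pair the pools. Deviations of the 15 same-number pairs correlated between -0.183 and 0.226, 4 of them over 0.1. Their mean was 0.012, against -0.003 over different numbers, and 3 of 15 libraries correlated best with their own number. Such values show no clear pairing but cannot exclude it.

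The share of lower genes at an unadjusted p under 0.05 reversed for corticosterone against control with total-count scaling (22.8%) and no low-count filter (49.9%), and for corticosterone against testosterone with total-count scaling (31.7%). For testosterone against control it ran from 40.9% to 51.2% with 1 library left out. Total-count scaling shifted the median gene by 0.05 log2 units after corticosterone. The counts themselves ran from 825 to 2042, 371 to 1024, 570 to 1376 and 655 to 1419 over the alternatives, in the order of comparisons above.

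The correlation between the hormones' fold changes was 0.150 with the controls divided, by construction without shared libraries, and 0.304 (without testosterone replicate 2) to 0.606 with 1 library left out. The 4 printed genes kept their direction in every alternative that tested them (28, and 27 for ENSGALG00000009006). They were picked for small p in these same libraries, so a reversal was unlikely and this is weak support.

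The gene list tests and all their alternatives were not run, as no identifier matched a symbol, and a fit of 2 groups does not apply to the test of any difference. Depth limits genes of low abundance: under 1 CPM, the interval lay within 1.5-fold for 12.5% of genes for corticosterone against control, against 97.8% over 100 CPM.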

Other observations

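The count of shared DESeq2 calls was chosen after the result was seen, and the tests on abundant genes before it.

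Among genes over 100 CPM, more were lower than higher after corticosterone with TMM (276 and 59), RLE (260 and 63) and upper-quartile scaling (246 and 92). With total-count scaling fewer were lower than higher (138 and 244). That flip does not bear on abundant genes relative to rarer ones. The median log2 fold change was -0.019 over 100 CPM and 0.001 at 1 to 10 CPM with TMM, and 0.036 and 0.058 with total-count scaling. Scaling between libraries, a real shift and chance cannot be told apart as the source of the counts. A contrast that no scaling moves cannot weigh scaling against a real shift. That contrast, of abundant against rarer genes within each library, differed from control by -0.04 log2 units with an exact permutation p of 0.286. A hypothesis that corticosterone replicates 1 and 2 alone carry the difference was met: -22.7% of it was kept without them, and the remaining difference was 0.01 log2 units. The values of these 2 libraries were -0.09 and -0.12, and the other corticosterone libraries lay between 0.01 and 0.03. Both had already stood apart in the same counts. As they were the lowest of their group, leaving them out had to raise its mean, so the outcome is weak support. Over all genes at an unadjusted p under 0.05, the share of lower genes was 59.7% without the 2 pools and 60.4% with them.

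The root mean square log2 distance of a pool to the other replicates of its group was 0.291 ± 0.025 after corticosterone and 0.255 ± 0.027 in controls (SD, n = 5). The 5 values of a group share pairs of pools, so no p is given for the difference.

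DESeq2 gave an adjusted p in both corticosterone comparisons to 2454 genes. Among these it called 13 as lower against control and 20 as lower against testosterone, with 4 genes in common, where independent lists would share 0.106. Both comparisons use the same corticosterone libraries, which alone raises such an overlap.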
